A study of Mus musculus with 4 samples.

How the data were processed

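Gene expression was measured by RNA sequencing in 4 liver samples, 2 from saline-gavaged and 2 from SWTX-gavaged male mice labelled Apoe-/-. Per the labels, RNA was purified with Trizol and libraries were made with the VAHTS Universal V6 kit for Illumina. The submitters' processing notes name HISAT2 2.2.1 and featureCounts, the latter without a version, and the genome builds GRCm39 and mm10 without the role of either. The annotation, the strand setting and any filter on genes are not given in the sources used here. Because the build is open, genes are identified by Ensembl identifier and symbol and no coordinates are given. The deposited table holds raw counts per Ensembl gene, 1 column per sample, which were checked to be whole numbers whose totals differ between samples.

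The table lists 27457 genes, of which 1033 had no count in any library and 438 had an identifier without a symbol. Total counts were 32570065 and 29384670 for the saline livers and 32111411 and 38603791 for the SWTX livers. These totals set the smallest level that can be seen, for which only counting error is considered. Intervals of fold changes come from the fit and include the spread between the livers of a group. The labels do not say whether the samples of a group are separate animals or pools, so that every p measures the spread between these samples. The sample numbers are not said to pair livers across groups, and no pairing was used.

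Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 15442, and libraries were scaled by TMM. A quasi-likelihood model with group as its only term was fitted with robust dispersion estimation, and SWTX was compared with saline by the quasi-likelihood F test. The common biological coefficient of variation was 0.191. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. CPM values are read counts scaled by the TMM-adjusted library size, fold changes are SWTX over saline unless given as a fall, standard errors are the absolute log2 fold change divided by the square root of F, and intervals are 95% intervals of the fit.

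The 17 core genes and 34 lists of pathway genes and cell type markers (556 symbols, 9 of them absent from the table) were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives. The lists cover cholesterol, bile acid and lipid metabolism, inflammation, the other cell types of liver, contaminating tissues, zonation, xenobiotic and stress responses, the clock, the cell cycle, sex-biased genes and mitochondrial transcripts. Lists were tested with camera (preset correlation 0.01, adjusted over the 34 lists), with camera using a correlation estimated per list, and with fry. Members were counted both past the threshold over all genes and adjusted over the list alone. The adjustment over the list alone was not corrected for the number of lists. Named genes are the 10 rising and the 10 falling genes of smallest p among called genes with a mean log2 CPM of at least 1 and an approved symbol, the 4 members of smallest p in each list, the core genes and Apoe, and the members behind any list count of 5 or fewer. Some genes that meet this rule are left unnamed and stand only in the counts. Saa1, Saa2, Fasn, Cyp2b10, Cd68, Trem2, Gpnmb and, in the closing section, Pdk4 fall outside this rule and were chosen after their values were seen. List medians per liver used log2 CPM with a pseudocount of 0.5 relative to the saline mean.

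Reads shared by close paralogs (Cyp2c, Cyp2a, Cyp4a, Hsd3b, Gstm, Saa, Hamp and Mup genes) cannot be separated in counts per gene, and neither can antisense or overlapping transcripts with an unknown strand setting. The alternatives were DESeq2 size factors (RLE) and upper-quartile factors, no filter and a filter of 10 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, non-robust dispersion, the sample number as a block, a 2-fold threshold, and leaving out each library. The tests were tried on simulated data of the same design, with 200 of 15442 genes changed. The filter left 15188 genes and removed 2 of the changed ones. In that step 2 of 66 genes changed 1.5-fold, 26 of 67 changed 2-fold and 51 of 65 changed 4-fold were recovered, and 4 of the 83 calls were unchanged genes. A simulated list raised as a whole had p = 6.6e-47 with the preset and p = 0.0040 with an estimated correlation, and an unchanged list had p = 0.44 and 0.51. Each gene was drawn at the dispersion trend of the fit, without the spread of real genes around that trend. Genes were drawn independently and with the same spread in both groups, whereas the estimated correlation of the real lists reached 0.985. The simulated lists therefore cannot show how the preset behaves when members move together.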

Results

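RNA sequencing of liver was deposited for 4 samples from mice labelled as male and Apoe-/-, a genotype that targets apolipoprotein E, a ligand for the hepatic uptake of lipoprotein remnants. The animals had a C57BL/6J background, were 8 weeks old at the start, and ate a Paigen diet for 8 weeks. This atherogenic chow contained cholesterol at 12.5 g/kg and the bile salt sodium cholate at 5 g/kg. A control group (n = 2) was gavaged with saline, and a treated group (n = 2) was gavaged with 3.5 g/kg per day of San-wei-tan-xiang (SWTX), a herbal medicine in capsule form. Assigned counts came to 32570065 and 29384670 in saline livers 1 and 2, and to 32111411 and 38603791 in SWTX livers 1 and 2. A single count therefore equalled 0.0247 to 0.0360 CPM, the read count scaled to library size. Between 21754 and 22850 genes had at least a single count in a library.

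Apoe itself (ENSMUSG00000002985) was counted in every liver labelled Apoe-/-, at 810 and 800 CPM in the saline livers and 643 and 864 CPM in the SWTX livers, which ranked it between place 126 and place 164 among all genes. Counts per gene cannot say which exons the reads came from, and the labels do not give the deleted part of the gene. The Apoe level did not differ detectably between the groups (log2 fold change -0.10 ± 0.17 SE, 95% interval -0.51 to 0.32, adjusted p = 0.824). Across genes, log2 CPM correlated at r = 0.991 between the saline livers, at 0.974 between the SWTX livers, and at 0.964 to 0.975 between livers of different groups. The SWTX livers differed from each other by over 2-fold in 1332 genes, against 403 for the saline livers.

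The comparison of SWTX with saline asks which liver transcripts differed between the groups, and the series title points to HDL-driven biliary cholesterol transport. In SWTX livers Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose 7.69-fold from 1.62 ± 0.0557 to 12.4 ± 4.38 CPM (mean ± SD, n = 2 livers per group here and in what follows). Lower levels were measured for 25 of 26 acute phase genes, 14 of 16 macrophage markers, all 7 measured genes of MHC class II antigen presentation and 14 of 20 chemokine, cytokine and adhesion genes, while the interferon list did not pass (adjusted p = 0.158). Targets of the xenobiotic receptors CAR, PXR and AhR were higher in 17 of 20 cases, and PPAR-alpha targets, which serve fatty acid oxidation, were lower in 26 of 30. Each of these list calls was lost with a correlation estimated per list (adjusted p = 0.68 with an estimated correlation). That setting has little power with 2 livers per group. Clock genes shifted in both directions, with a 5.79-fold rise of Per2 and a 7.79-fold fall of Arntl. The labels give neither the hour of collection nor the feeding state. Differences in genes that follow either, Cyp7a1 and lipid genes not excepted, therefore cannot be assigned to SWTX alone.

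Of 15442 genes tested with edgeR, 118 changed, 47 upwards and 71 downwards, with absolute log2 fold changes from 0.86 to 5.79, and 112 of them changed at least 2-fold. The unadjusted p was under 0.05 for 2481 of the 15442 genes, which is the background for the unadjusted counts given for single lists below. The count depended on single libraries, being 9 without saline liver 1, 5 without saline liver 2, 3494 without SWTX liver 1 and 3838 without SWTX liver 2. All 118 genes kept their sign in each of these fits, but the groups did not overlap in any of the 118. A kept sign therefore follows from their selection and is no check of the calls. Of the 40 genes named here and below that passed over all genes, 6 still passed without saline liver 1 (Per2, Car3, Ly6d, Cd14, Insig2 and Cdkn1a), 4 without saline liver 2 (Car3, Ly6d, Cd14 and Cdkn1a), and 40 without SWTX liver 1 or 2. DESeq2 called 728 genes and limma-voom 63.

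The rising genes of smallest p were led by Per2 (ENSMUSG00000055866), a repressor of the circadian clock, which went from 11.8 ± 0.412 to 68.3 ± 6.75 CPM (log2 fold change 2.53 ± 0.15 SE, adjusted p = 0.00509). Srebf1 (ENSMUSG00000020538), which encodes the transcription factor SREBP1 of fatty acid synthesis, rose 4.66-fold to 382 ± 16.9 CPM (log2 fold change 2.22 ± 0.13, adjusted p = 0.00509). Car3 (ENSMUSG00000027559), a carbonic anhydrase, showed the widest change among these genes, from 9.16 ± 0.427 to 208 ± 67.1 CPM (log2 fold change 4.50 ± 0.27, adjusted p = 0.00578). The drug-metabolising Cyp2c29 (ENSMUSG00000003053) rose 3.64-fold to 1636 ± 48.7 CPM (adjusted p = 0.00759). Gamt, which makes creatine, Noct, a rhythmically expressed phosphatase, Coq10b, a coenzyme Q binding protein, the steroid dehydrogenase Hsd3b3 and the cytochrome Cyp2c55 rose by 2.49-fold, 4.94-fold, 2.63-fold, 2.69-fold and 4.87-fold (adjusted p from 0.0215 to 0.0281). Reads of Cyp2c and Hsd3b genes can be shared with close paralogs, so that these counts may include reads of their relatives.

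Among the falling genes, Ly6d (ENSMUSG00000034634), a surface protein of the Ly6 family, dropped 14.8-fold from 57.6 ± 0.690 to 3.90 ± 1.0 CPM (log2 fold change -3.89 ± 0.21, adjusted p = 0.00509). Cd14 (ENSMUSG00000051439), a co-receptor for bacterial lipopolysaccharide, fell 5.69-fold from 40.8 ± 1.25 to 7.18 ± 0.748 CPM (adjusted p = 0.00509). Insig2 (ENSMUSG00000003721), which holds the SREBP complex in the endoplasmic reticulum, fell 4.17-fold from 353 ± 1.97 to 84.5 ± 1.32 CPM (log2 fold change -2.06 ± 0.13, adjusted p = 0.00509). The cell cycle inhibitor Cdkn1a fell 5.53-fold (adjusted p = 0.00578). The neutrophil chemokine Cxcl1, the citrate transporter Slc13a5, the myeloid receptor Cd300e, the protease inhibitor Serpina3n and the mitochondrial protease subunit Clpx fell by 2.87-fold, 3.03-fold, 5.75-fold, 3.37-fold and 2.92-fold (adjusted p = 0.0180 for each).

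**Figure D1:**
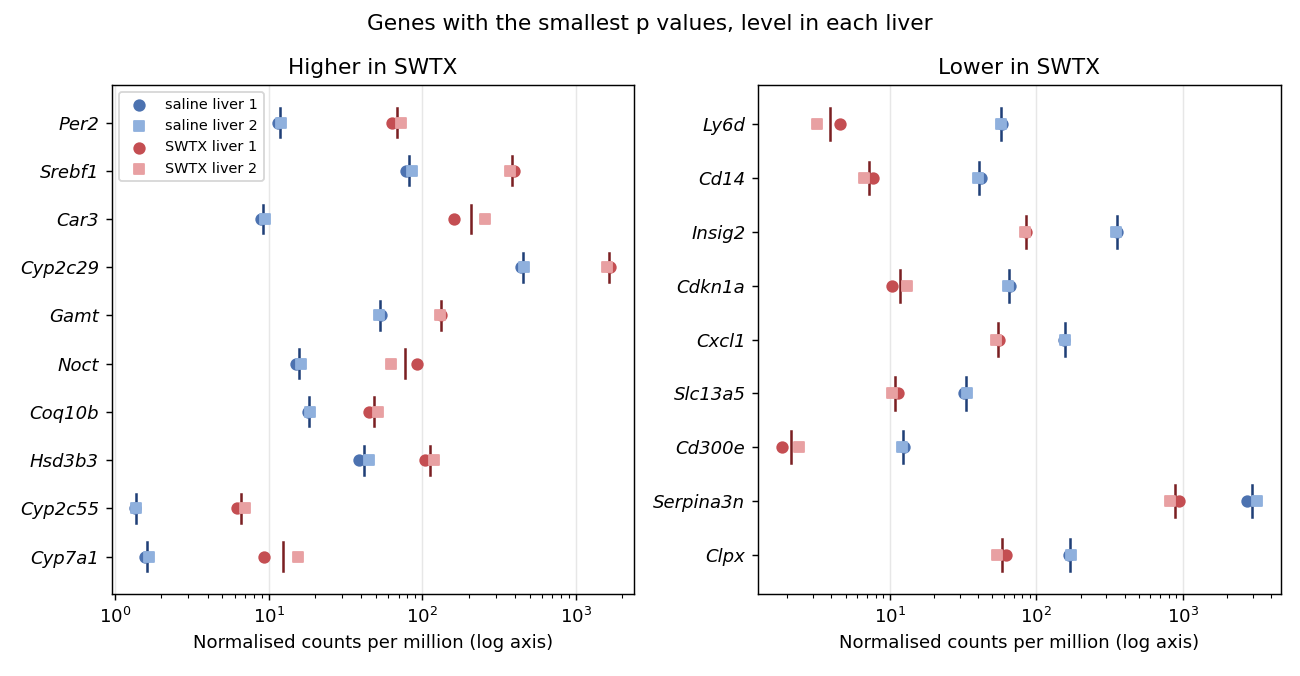
Normalised read counts (CPM) on a log axis for the named rising (left) and falling (right) genes of smallest p, with a point per liver and a vertical line at each group mean (n = 2 livers per group). The livers of the groups do not overlap for any of these genes, as with Ly6d, whose means are 57.6 and 3.90 CPM.

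Of the 17 core genes of hepatic and biliary cholesterol transport, 2 passed over all genes tested and 7 passed adjusted over the list alone. Cyp7a1 (ENSMUSG00000028240) rose with a log2 fold change of 2.94 ± 0.31 (adjusted p = 0.0281). Its adjusted p was 0.181 without saline liver 1 and 0.196 without saline liver 2, where 0 core genes passed, with 5 at an unadjusted p under 0.05 in either case. The count was 12 without SWTX liver 1 and 9 without SWTX liver 2. Of the 7 that passed over the list, 3 were higher and 4 lower. The lower ones included Abcb4, the canalicular phospholipid transporter (472 ± 30.8 to 278 ± 20.3 CPM, log2 fold change -0.77 ± 0.13), and Nr0b2, which encodes the repressor SHP (-0.96 ± 0.21). The others were the HDL receptor Scarb1 (-0.43 ± 0.13) and the sterol hydroxylase Cyp27a1 (-0.40 ± 0.13). The adjusted p of these 4 genes ran from 0.0746 to 0.206 over all genes and from 0.00433 to 0.0402 over the list.

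For the other 10 core genes no difference was detectable. Apoa1, the main HDL protein, had a 95% interval of the log2 fold change of -0.48 to 0.50, and its change was -0.29 without SWTX liver 1 (adjusted p = 0.0151) and 0.25 without SWTX liver 2 (adjusted p = 0.00347). The intervals were -0.46 to 0.22 and -1.12 to 0.34 for the cholesterol exporters Abca1 and Abcg1, and -0.47 to 0.15 for Lcat, which esterifies cholesterol on HDL. They were -0.27 to 0.73 for Abcg5 and -0.39 to 0.69 for Abcg8, whose products form the canalicular sterol transporter, and -0.87 to 0.37 for the bile salt pump Abcb11. For these 3 genes SWTX livers 1 and 2 lay on opposite sides of both saline livers. Abcg5 was at 195 and 292 CPM against 202 and 213 in saline, Abcg8 at 164 and 257 against 181 and 198. Abcb11 was at 479 and 285 CPM against 433 and 475. The intervals of the nuclear receptors Nr1h3 (LXR-alpha) and Nr1h4 (FXR) were -0.28 to 0.34 and -0.12 to 0.64. Cyp8b1, the sterol 12-alpha-hydroxylase, was low in both groups (13 to 22 counts per library), at 0.653 ± 0.0580 and 0.462 ± 0.199 CPM (interval -1.63 to 0.60). In data simulated with the same design, 38.8% of genes changed 2-fold and 3.03% of genes changed 1.5-fold were recovered. These shares are for adjustment over all genes with the same spread in both groups, and do not apply to adjustment over the list alone. Simulated genes also lacked the spread of real genes around the dispersion trend, and only 200 were changed. The shares therefore need not hold for the real genes.

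**Figure D2:**
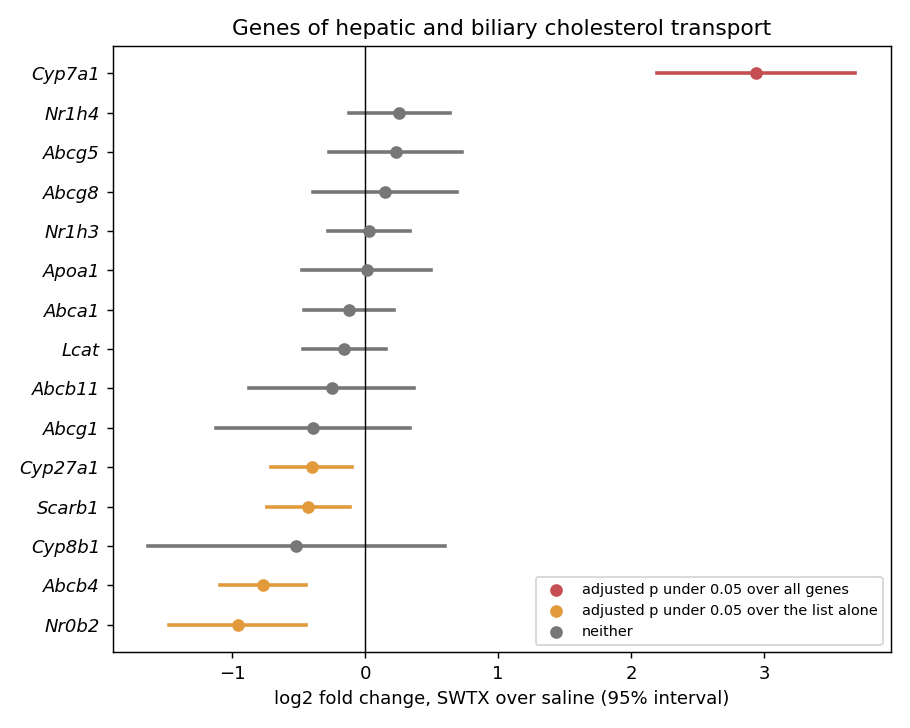
Log2 fold change of SWTX over saline for the core genes named in the text, with a point for the estimate and a line for its 95% interval (n = 2 livers per group). Cyp7a1, at 2.94, passes over all genes, and the estimates of Apoa1, Abca1, Lcat, Abcg5 and Abcg8 lie between -0.16 and 0.23 with intervals across 0.

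The 34 gene lists, fixed before the data were examined, were compared with all other genes by limma's camera, and 16 differed, 8 higher and 8 lower. With an estimated correlation between members 0 of the 34 passed (smallest unadjusted p 0.083). By fry, a rotation test of each list by itself, 0 passed (smallest adjusted p 0.35), while fry's test for change in either direction called 14. Fits that left out a library used the preset correlation with a lone liver in a group. Their adjusted p values take members that move together as nearly independent and do not measure spread in that group. The HDL particle and reverse cholesterol transport list held 5 higher and 11 lower of 16 genes. Its median log2 fold change was -0.15 (adjusted p = 0.218), and -0.26 without SWTX liver 2. Over all genes 0 members passed, with 5 at an unadjusted p under 0.05. The same 5 passed adjusted over the list alone, upwards the paraoxonase Pon1 (log2 fold change 0.57) and the lipase Lipg (0.81), downwards Apoa4 (-1.12), Apom (-0.50) and Scarb1.

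Of 25 genes of cholesterol synthesis and the SREBP2 pathway, 20 were higher (median log2 fold change 0.30, adjusted p = 0.000352; adjusted p = 0.68 with an estimated correlation). Over all genes 1 member passed upwards and 0 downwards, and adjusted over the list alone 5 were higher and 1 lower. The higher ones included the sterol carrier Stard4 (log2 fold change 1.12), the SREBP inhibitor Insig1 (1.29) and the cyclase Lss (0.86), and the lower one was the synthase Hmgcs1 (52.0 ± 0.621 to 37.2 ± 0.212 CPM, -0.48). The list rested on SWTX liver 1, which was highest of the 4 livers in 16 of the 25 genes, and without it the median was -0.04 (adjusted p = 0.136); without SWTX liver 2 the median was 0.56. Bile acid synthesis genes were higher in 6 and lower in 9 of 15 cases (adjusted p = 0.450), with a median of -0.09 but a mean of 0.21 and a test direction upwards, and a median of -0.21 without SWTX liver 1. Cyp7a1 passed over all genes. With it, the aldo-keto reductases Akr1c6 (0.65) and Akr1d1 (1.4) were higher adjusted over the list alone, and Acot8 (-0.70) and Cyp27a1 were lower. In the list of 15 bile transporters (8 higher, 7 lower, median 0.07, adjusted p = 0.412, and median -0.13 without SWTX liver 2) the organic anion importer Slco1a4 rose 5.39-fold from 16.6 ± 0.280 to 89.5 ± 34.6 CPM (adjusted p = 0.0404). Slco1a4 was higher and Abcb4 lower adjusted over the list alone.

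Genes of fatty acid and triglyceride synthesis were higher in 15 of 20 cases (median log2 fold change 0.37, adjusted p = 7.01e-06; adjusted p = 0.68 with an estimated correlation), with a median of 0.23 without SWTX liver 1. Srebf1, the lipogenic regulator Thrsp (14.9 ± 0.966 to 167 ± 85.7 CPM, adjusted p = 0.0436) and the phosphatidate phosphatase Lpin1 (2.44-fold, adjusted p = 0.0429) rose over all genes, the log2 fold change of Thrsp being 3.48 and, without SWTX liver 1, 2.83. The counts adjusted over the list alone were 4 higher and 2 lower, which added the elongase Elovl6 (1.10) and, downwards, the desaturase Scd1 (7399 ± 582 to 4089 ± 852 CPM, -0.86) and Elovl5 (-0.85). The synthase gene Fasn was at 102 ± 14 and 307 ± 205 CPM and did not pass (adjusted p = 0.249). In the apoB lipoprotein and lipase list (9 higher, 7 lower of 16, median 0.04, adjusted p = 0.631, and medians from 0.0032 to 0.08 when a library was left out) Angptl8, an insulin-induced inhibitor of lipoprotein lipase, rose 6.08-fold to 284 ± 107 CPM (adjusted p = 0.0317). Angptl8 was among 2 genes that were higher adjusted over the list alone, and 3 genes were lower, the editing enzyme Apobec1 (-0.71), the remnant receptor Lrp1 (-0.72) and the lipase Lpl (-0.58).

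PPAR-alpha targets and fatty acid oxidation genes were lower in 26 of 30 cases (median log2 fold change -0.42, adjusted p = 2.77e-09; adjusted p = 0.68 with an estimated correlation). The median was -0.26 without SWTX liver 1 and -0.75 without SWTX liver 2. Crot, a peroxisomal carnitine acyltransferase, fell 2.61-fold from 993 ± 31.1 to 380 ± 53.7 CPM (adjusted p = 0.0281), and the fasting hormone Fgf21 fell 3.38-fold (adjusted p = 0.0495). There were 7 lower and 0 higher members adjusted over the list alone, among them the lipid droplet protein Plin2 (-1.29) and the omega-hydroxylase Cyp4a14 (-1.17). Glucose metabolism genes were higher in 10 of 15 cases (median 0.34, adjusted p = 0.252, and median 0.18 without SWTX liver 1 and 0.19 without SWTX liver 2), with 0 past the threshold over all genes and 8 at an unadjusted p under 0.05. The transporter Slc2a2 (0.72) and the kinases Pklr (0.86) and Pfkfb1 (0.53) were higher adjusted over the list alone, and Gpd1 (-0.87) and Igfbp1 (-2.77) were lower.

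Of 20 targets of CAR, PXR and AhR, 17 were higher (median log2 fold change 1.12, adjusted p = 4.50e-13; adjusted p = 0.68 with an estimated correlation). Cyp2c29, Cyp2c50 (2.25-fold), Cyp2c54 (2.06-fold), Cyp2c55 and the carboxylesterase Ces2a (118 ± 2.03 to 248 ± 1.87 CPM) rose over all genes. The list median was 1.21 without SWTX liver 1 and 0.79 without SWTX liver 2. The count adjusted over the list alone was 11 higher and 0 lower. Cyp2b10, a common marker of CAR activity, was at 0.185 ± 0.00655 CPM in saline and 26.2 ± 24.9 CPM in SWTX livers and passed only adjusted over the list alone (adjusted p = 0.128 over all genes). NRF2 targets, which serve antioxidant defence, were higher in 9 of 15 cases (median 0.08, adjusted p = 0.0130; adjusted p = 0.68 with an estimated correlation), and the list did not pass without SWTX liver 2 (median -0.03, adjusted p = 0.404). Its median was 0.24 without saline liver 1, 0.21 without saline liver 2 and 0.38 without SWTX liver 1. The glutathione transferases Gstm1 (898 ± 14 to 2236 ± 262 CPM) and Gstm3 (2.19-fold) rose over all genes. With Gsta2 (2.28) and Gsta4 (0.64) they were higher adjusted over the list alone, and the dehydrogenase G6pdx (-0.69) was lower.

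Hepatocyte identity genes were higher in 11 of 16 cases (median log2 fold change 0.18, adjusted p = 0.450). Over all genes 1 rose and 0 fell. Adjusted over the list alone 5 were higher and 3 lower. Cps1 (0.82), Hpd (0.52), Asgr2 (0.37) and Ttr (0.38) were among the higher ones, while the glucose-6-phosphatase G6pc (-1.33), Trf (-0.68) and Ambp (-0.62) were lower. Pericentral genes were split 7 to 7 of 14 (median -0.05, mean 0.03, test direction upwards, adjusted p = 0.833), with a 2.60-fold rise of Cyp1a2, an AhR-induced cytochrome (adjusted p = 0.0455). The pericentral median was -0.08 without saline liver 1, 0.04 without saline liver 2, 0.05 without SWTX liver 1 and -0.175 without SWTX liver 2. Cyp1a2 and Lect2 (0.74) were higher adjusted over the list alone, and Tbx3 (-0.69) and the glutamine synthetase Glul (-0.52) lower. Among 13 periportal genes 10 were higher (median 0.17, adjusted p = 0.541, and median 0.11 without SWTX liver 1), and the protease Ctsc fell 2.29-fold (adjusted p = 0.0281). Ass1 (0.74) and Gls2 (0.68) were higher and Ctsc lower adjusted over the list alone.

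Acute phase genes, which the liver induces in inflammation, were lower in 25 of 26 cases (median log2 fold change -1.05, adjusted p = 4.0e-22; adjusted p = 0.68 with an estimated correlation). The list median was -0.84 in SWTX liver 1 and -1.43 in SWTX liver 2 relative to the saline mean. Serpina3n, Itih3 (4797 ± 444 to 2066 ± 357 CPM) and Itih4 (7716 ± 772 to 3882 ± 38.6 CPM) fell over all genes. The count adjusted over the list alone was 21 lower and 1 higher. The gene that rose was Hamp, which encodes the iron hormone hepcidin, by 9.25-fold from 76.2 ± 5.27 to 705 ± 347 CPM (adjusted p = 0.0436), with a log2 fold change of 3.21 and, without SWTX liver 1, of 2.59. The serum amyloid genes Saa1 (6023 ± 484 to 817 ± 820 CPM) and Saa2 (5132 ± 538 to 445 ± 526 CPM) varied too much between the SWTX livers to pass (adjusted p = 0.309 and 0.360). Complement and coagulation genes were lower in 18 of 21 cases (median -0.19, adjusted p = 0.0130; adjusted p = 0.68 with an estimated correlation), and the list did not pass without SWTX liver 2 (median -0.16, adjusted p = 0.129). Its median was -0.30 without saline liver 1 and -0.12 without saline liver 2. Over all genes and adjusted over the list alone 0 members passed, with 3 at an unadjusted p under 0.05, all lower.

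Chemokine, cytokine and adhesion genes were lower in 14 of 20 cases (median log2 fold change -0.31, adjusted p = 0.000984; adjusted p = 0.68 with an estimated correlation), with medians of -0.50 without SWTX liver 1 and -0.47 without SWTX liver 2. Cxcl1 fell over all genes from 156 ± 1.91 to 54.5 ± 1.5 CPM. Cxcl1, the inflammasome sensor Nlrp3 (-1.32), the NF-kappa-B feedback genes Nfkbia (-0.77) and Tnfaip3 (-0.99) and the monocyte receptor Ccr2 (-1.0) were lower adjusted over the list alone, and the chemokine Cxcl10 (0.91) was higher. Interferon response genes were lower in 14 of 18 cases (median -0.26, adjusted p = 0.158). The list median was -0.14 without saline liver 1, -0.31 without saline liver 2, -0.17 without SWTX liver 1 and -0.38 without SWTX liver 2. Of its members 0 passed over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05, of which Igtp (0.41) was higher and Irf7 (-0.42) and Rsad2 (-0.51) were lower. All 7 genes of MHC class II presentation were lower (median -0.71, adjusted p = 1.80e-05; adjusted p = 0.68 with an estimated correlation), with a median of -0.47 without SWTX liver 1. Over all genes 0 of them passed, and 7 passed adjusted over the list alone, such as the class II transactivator Ciita (-0.94).

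Macrophage and Kupffer cell markers were lower in 14 of 16 cases (median log2 fold change -0.80, adjusted p = 2.77e-09; adjusted p = 0.68 with an estimated correlation). The list median relative to saline was -1.06 in SWTX liver 1 and -0.59 in SWTX liver 2. Marco, a scavenger receptor of resident macrophages, fell 2.99-fold from 59.4 ± 3.11 to 19.9 ± 4.21 CPM (adjusted p = 0.0300). There were 11 lower and 0 higher markers adjusted over the list alone, among them the Kupffer cell lectin Clec4f (252 ± 31.1 to 78.5 ± 26.0 CPM), Csf1r (-0.94) and C1qa (-0.78). Cd68, at 75.1 ± 1.39 and 64.1 ± 19.9 CPM, and Trem2, at 24.3 ± 2.34 and 21.6 ± 9.94 CPM, did not pass, nor did Gpnmb, a gene of lipid-laden macrophages, at 109 ± 1.18 and 219 ± 143 CPM. All 10 neutrophil markers were lower (median -0.95, adjusted p = 1.80e-05; adjusted p = 0.68 with an estimated correlation), with a median of -0.50 without saline liver 1. Over all genes 0 passed, and 4 passed adjusted over the list alone, namely the granule genes Elane (-2.22), Ngp (-1.18), Mpo (-1.97) and Ltf (-1.27). Lysosomal genes were lower in 15 of 17 cases (median -0.22, adjusted p = 0.156). Their median was -0.44 without SWTX liver 2 and -0.05 without SWTX liver 1. Of the lysosomal genes 0 passed over all genes or adjusted over the list alone, with 5 at an unadjusted p under 0.05.

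Stellate cell and matrix genes were higher in 14 of 16 cases (median log2 fold change 1.18, adjusted p = 0.000305; adjusted p = 0.68 with an estimated correlation). SWTX liver 2 was the highest of the 4 livers in 13 of the 16, and without it the median was 0.44 (adjusted p = 0.0930). Without saline liver 1 that median was 1.70, and without saline liver 2 it was 0.65. Over all genes 0 members passed, with 6 at an unadjusted p under 0.05. Acta2 (1.31) was higher adjusted over the list alone and the basement membrane collagen Col4a1 (31.6 ± 0.572 to 16.8 ± 1.39 CPM, -0.91) was lower. Sinusoidal endothelial markers were higher in 8 of 11 cases (median 0.52, adjusted p = 0.165), with 0 members past either adjustment or at an unadjusted p under 0.05. The endothelial median was 0.95 without saline liver 1 and 0.89 without SWTX liver 1, but 0.18 without saline liver 2 and -0.02 without SWTX liver 2. T, B and NK cell markers were higher in 8 of 12 cases (median 0.26, adjusted p = 0.158), with 0 members past either adjustment and 1 at an unadjusted p under 0.05. Levels were low, with Cd79a, Cd79b and Cd3e all under 1 CPM. For the T, B and NK list the median was 0.79 without saline liver 1 and 0.89 without SWTX liver 1. It was 0.12 without saline liver 2 and -0.17 without SWTX liver 2. Cholangiocyte markers were higher in 4 and lower in 6 cases (median -0.19, adjusted p = 0.221, and medians from -0.31 without SWTX liver 2 to 0.04 without SWTX liver 1). Over all genes 0 passed, with 3 at an unadjusted p under 0.05, and 2, among them Sox9 (-1.03), were lower adjusted over the list alone. All 6 red blood cell markers were lower (median -0.15, adjusted p = 0.158), with medians from -0.08 without saline liver 1 to -0.40 without SWTX liver 2. Over all genes 0 of them passed, and only Slc4a1 (-1.63) passed adjusted over the list alone. Of 15 markers of pancreas, muscle and fat only Cela2a and Cfd were abundant enough to test, both under 1 CPM (median -0.48, adjusted p = 0.470, and medians from -1.99 without SWTX liver 2 to 1.24 without saline liver 2), and 0 passed in either adjustment or at an unadjusted p under 0.05.

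**Figure D3:**
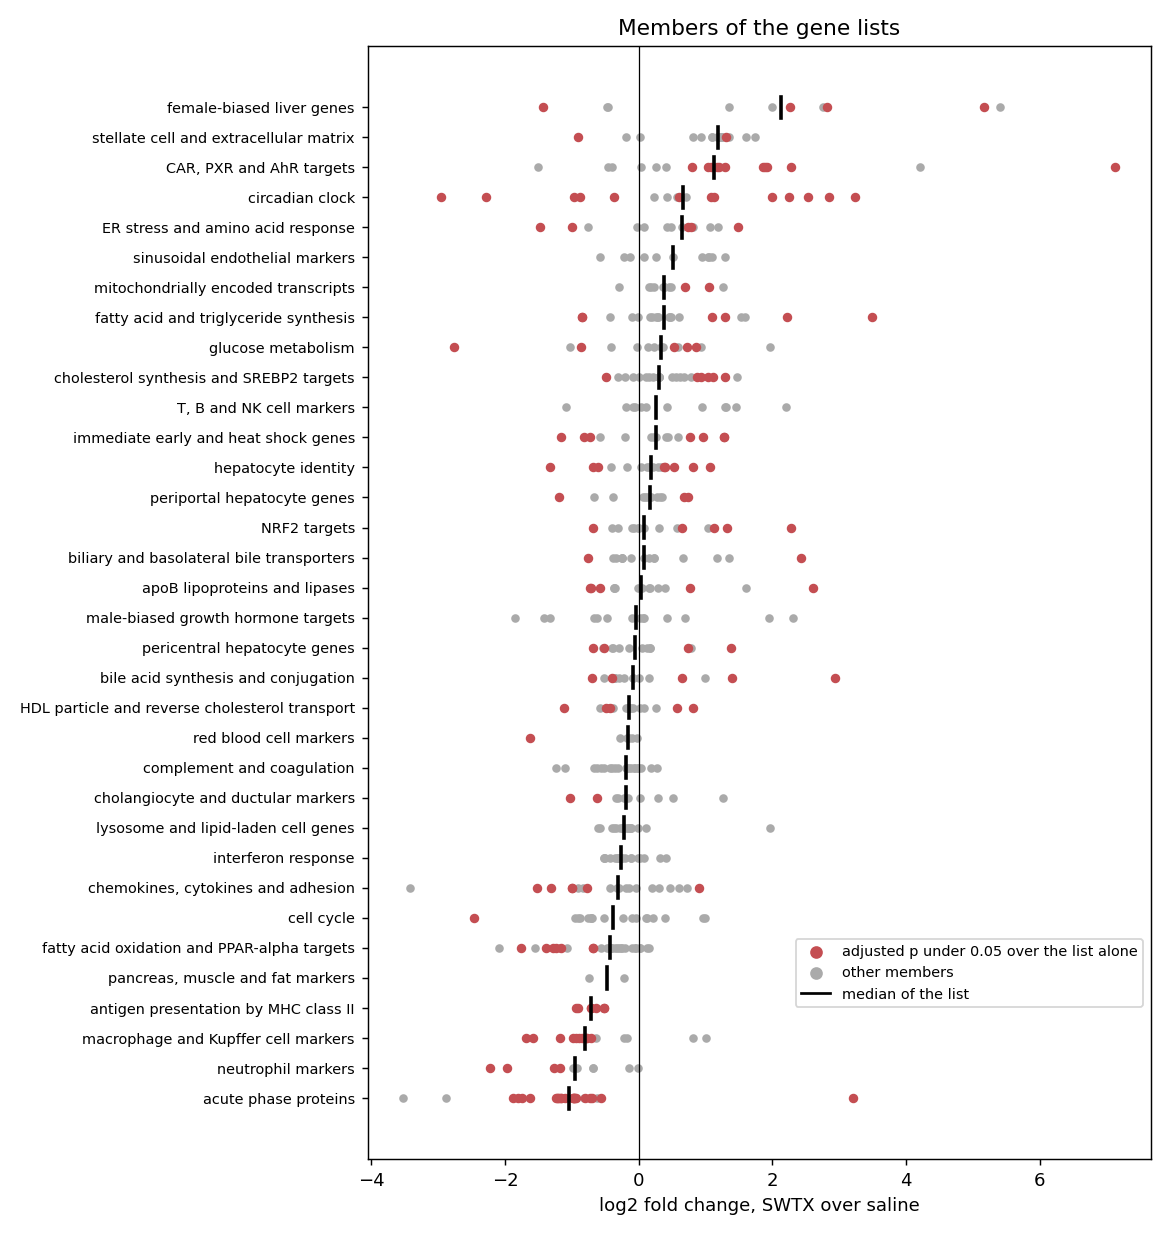
Log2 fold change of SWTX over saline for each tested member of the 34 lists (a point per gene), with a black line at each list's median and red points for members past the threshold over their list alone. Acute phase genes have a median of -1.05 with Hamp apart at 3.21, and CAR, PXR and AhR targets have a median of 1.12.

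Clock genes were higher in 13 of 18 cases (median log2 fold change 0.66, adjusted p = 1.15e-05; adjusted p = 0.68 with an estimated correlation), with a median of 0.33 without SWTX liver 2. Per2, the output regulator Dbp (16.9 ± 0.579 to 67.0 ± 23.3 CPM, adjusted p = 0.0430) and the deubiquitinase Usp2 (7.22-fold, adjusted p = 0.0444) rose, and the activator Arntl, also called Bmal1, fell from 9.06 ± 0.988 to 1.17 ± 0.393 CPM (adjusted p = 0.0269). The counts adjusted over the list alone were 8 higher and 5 lower, the latter being Arntl, Npas2 (-2.29), Nfil3 (-0.98), Clock (-0.88) and Nr1d1 (-0.38). Cell cycle genes were lower in 12 of 18 cases (median -0.38, adjusted p = 0.0150; adjusted p = 0.68 with an estimated correlation), with medians of -0.06 without saline liver 1, -0.13 without SWTX liver 1 (adjusted p = 0.602) and -0.81 without SWTX liver 2. Its only member past either adjustment was Cdkn1a, which halts the cycle rather than driving it. Mitochondrially encoded transcripts were higher in 12 of 13 cases (median 0.38, adjusted p = 0.00107; adjusted p = 0.68 with an estimated correlation), and the list did not pass without saline liver 1 (median 0.27, adjusted p = 0.100). Over all genes 0 passed, and mt-Co2 (0.69) and mt-Co3 (1.05) passed adjusted over the list alone. The mitochondrial share of all counts was 3.45% and 3.66% in the saline livers and 5.04% and 4.64% in the SWTX livers.

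ER stress and amino acid response genes were higher in 11 of 15 cases (median log2 fold change 0.64, adjusted p = 0.189), with 0 past the threshold over all genes and 6 at an unadjusted p under 0.05. Herpud1 (0.74), Ddit3 (1.49) and Atf3 (0.78) were higher adjusted over the list alone, and Chac1 (-1.47) and Trib3 (-1.0) were lower. SWTX liver 1 was the highest of the 4 livers in 11 of the 15 genes. Without SWTX liver 2 the list median was 0.78, while without SWTX liver 1 it was -0.37. Immediate early and heat shock genes were higher in 10 of 15 cases (median 0.26, adjusted p = 0.624, and median 0.0056 without SWTX liver 1), with 0 past the threshold over all genes and 8 at an unadjusted p under 0.05. The heat shock genes Hsph1 (1.28), Hspa1b (0.96) and Dnajb1 (0.77) and the early gene Fosb (1.28) were higher adjusted over the list alone, and the early genes Dusp1 (-0.82), Zfp36 (-0.73) and Fos (-1.16) were lower.

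Sex-biased liver genes differed between the SWTX livers. Female-biased genes were higher in 7 of 10 cases (median log2 fold change 2.13, adjusted p = 0.00543; adjusted p = 0.68 with an estimated correlation), with a median of 0.80 without SWTX liver 2 (adjusted p = 0.000445). Relative to saline the list median was 0.33 in SWTX liver 1 and 2.70 in SWTX liver 2, and Cyp2a4 averaged 653 ± 669 CPM over the SWTX livers. Only Cyp4a31, a member of the Cyp4a family of PPAR-alpha targets, passed over all genes, and it fell 2.71-fold (adjusted p = 0.0281). Cux2 (2.27), Fmo2 (2.81) and Cyp2a4 (5.16) were higher adjusted over the list alone, and Cyp4a31 was lower. Male-biased targets of growth hormone were split 7 to 7 of 14 (median -0.04, adjusted p = 0.218), with 0 members past either adjustment or at an unadjusted p under 0.05. Their median was 0.46 in SWTX liver 1 and -2.14 in SWTX liver 2. The median log2 fold change of this list was -2.78 without SWTX liver 1, -0.09 without saline liver 1 and 0.46 without SWTX liver 2. Its members moved together (estimated correlation 0.985), so they are not independent observations of a change.

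**Figure D4:**
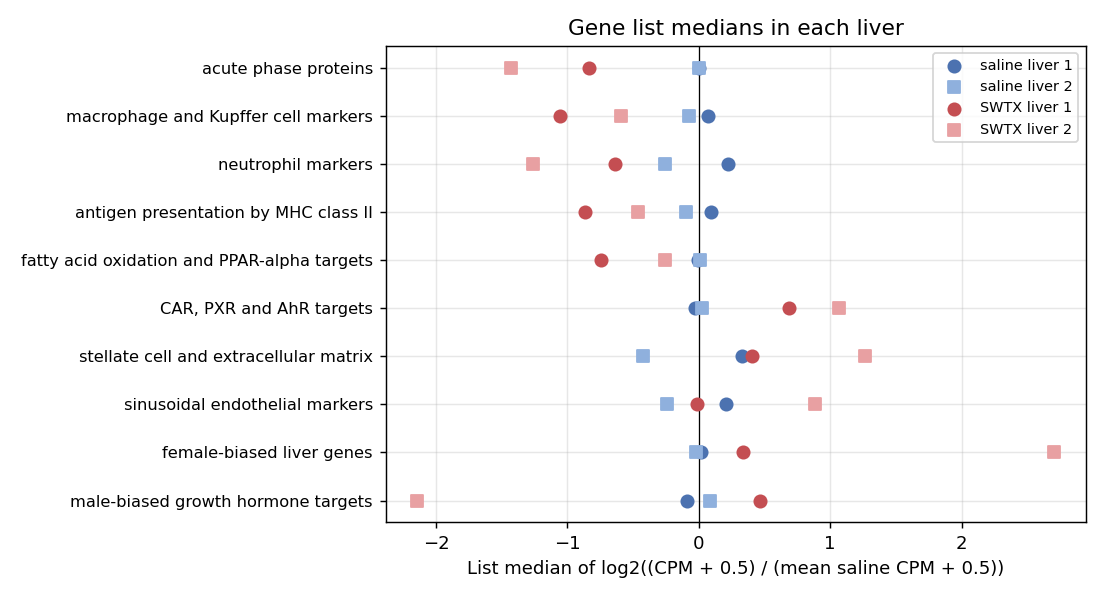
Median over the members of 10 gene lists of log2 CPM relative to the saline mean, with a pseudocount of 0.5 CPM and a point per liver (n = 2 livers per group). Both SWTX livers lie below both saline livers for acute phase genes (-0.84 and -1.43), and they lie on opposite sides of the saline livers for male-biased genes (0.46 and -2.14).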

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

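All settings here were planned. All 118 called genes kept their sign in every setting in which they were tested, the filter of 10 CPM leaving 93 of them. As the groups did not overlap in any of the 118, this was largely fixed by their selection. The number of genes called was 118 with TMM and stayed within 1.5 times of that with RLE factors, upper-quartile factors, non-robust dispersion and an added 2-fold threshold. It was 1540 without a filter, of which 1481 were among the 15442 genes of the filtered test, 69 with a filter of 10 CPM, 728 with DESeq2, 63 with limma-voom, 28 with the sample number as a block and 897 at an unadjusted p with a 2-fold change. Without a filter the prior degrees of freedom of the dispersion became infinite. Leaving out a library gave from 5 to 3838 genes, the low counts without a saline liver (coefficient of variation 0.261) and the high counts without a SWTX liver (0.0922), since the remaining pair then sets the spread and the lone liver is assumed to vary like it. Of the 118 genes, DESeq2 kept 118, limma-voom 62 and the block 25. The block is arbitrary, as the residuals of equally numbered livers correlated at -0.073. Of the 17 core genes, 5 passed without a filter, 1 with 10 CPM, 5 with DESeq2, 0 with limma-voom (7 at an unadjusted p under 0.05) and 1 with the block, and 0 to 12 when a library was left out. Of the 16 lists called, 0 passed with an estimated correlation, 0 by fry and 13 passed with 10 CPM. Over all 34 lists, 17 to 18 passed when a library was left out, with 13 to 16 of the 16 kept. When a library was left out, the median of the male-biased list ran from -2.78 to 0.461, and the log2 fold changes of Apoa1 and of the male-biased gene Hsd3b5 ran from -0.287 to 0.252 and from -3.83 to 3.3. Each turned its sign when a single SWTX liver was left out. Apoa1, at 0.011 with all livers, also turned without saline liver 2 (-0.0541). The cause was not tested.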

Other observations

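The tests of explanations in this part were all chosen after the results were seen. Some genes that respond to feeding and insulin changed, but not all in a single direction. Srebf1, Thrsp and Angptl8, which insulin induces, rose 4.66-fold, 11.2-fold and 6.08-fold (n = 2 livers per group). Adjusted over the lipogenic list alone 4 genes were higher, Elovl6 (1.10) among them, and 2 were lower, Scd1 (-0.86) and Elovl5 (-0.85). Fasn was higher on average but did not pass (adjusted p = 0.249). Insig2 and Fgf21, which are higher in fasting, fell. The fasting-induced genes Igfbp1 (275 ± 8.37 and 40.3 ± 33.6 CPM), Pdk4 (9.44 ± 0.0959 and 2.19 ± 1.86 CPM) and G6pc (255 ± 15.1 and 101 ± 29.6 CPM) were lower without passing over all genes (adjusted p = 0.204, 0.209 and 0.0668). Igfbp1 and G6pc were lower adjusted over their lists alone. This group was put together after the values were seen and has no test of its own.

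The clock genes moved by phase. Of 12 genes that peak in mouse liver by day or at dusk 11 were higher (median log2 fold change 1.10). Of 6 that peak late at night 4 were lower (median -0.93, two-sided Fisher's exact test, p = 0.0217). This test counts genes of a single clock as independent units, so its p does not measure the spread between livers. A different hour of collection or feeding state between the groups may account for the pattern, since the labels give neither. A direct effect of SWTX on the clock predicts the same values and stays open.

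Macrophage markers were lower in both SWTX livers. More hepatocyte RNA alone would lower every other cell type alike. The stellate median exceeded the macrophage median by at least 1.47 in the SWTX livers, against a range of 0.612 between the saline livers. The stellate list rose by itself, so this difference cannot exclude more hepatocyte RNA. Relative to saline, SWTX liver 1 had medians of -0.64 for neutrophil, -0.38 for red blood cell, -0.28 for cholangiocyte and -0.01 for endothelial markers. SWTX liver 2 had -1.26, -0.12, 0.03 and 0.89. A single even loss of all macrophages would give the 16 markers a common fold change, but Cochran's Q per degree of freedom was 4.83, where a common fold change gives a value near 1. More hepatocyte RNA, a loss of some macrophages and a lower expression per cell all stay open, as no test separated cell number from activity.

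Male-biased genes differed between the SWTX livers in opposite directions, liver 2 being the lowest of the 4 livers in 13 of 14 and liver 1 the highest in 11 of 14. The members moved together (estimated correlation 0.985), so that these counts are not independent observations. RNA from a female liver in SWTX liver 2 is argued against by Y-linked genes at 1.03 times the level of the other livers and by Xist counts of 2, 2, 4 and 1 in saline livers 1 and 2 and SWTX livers 1 and 2. Reads shared within the Mup, Cyp and Serpina1 families are argued against as the whole cause, since the 6 members outside them had a median log2 level of -2.10 relative to saline in SWTX liver 2, where no saline liver departed by more than 0.292, although Selenbp2 was not lower. No biological explanation was tested, and whether SWTX is involved cannot be judged from these livers.

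SWTX liver 2 was the highest of the 4 livers in 13 of 16 stellate and 10 of 11 endothelial markers, values given without an explanation.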
